A study of Mus musculus with 10 samples.

How the data were processed

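Achilles tendon RNA of 10 mice was measured by RamDA-seq on an Illumina NovaSeq instrument, in 3 Mkx-CreER/+, 4 Mkx-flox/+ and 3 Mkx-CreER/flox libraries. The deposited table holds raw counts per Ensembl gene for 32285 genes. Per the labels, the authors trimmed reads with fastp and aligned them with STAR to mm10. The versions, the counting tool, the annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Column names gave the genotype and a number. The Mkx-flox/+ columns were matched to samples by genotype and number. The Mkx-CreER/+ columns (1, 2 and 4) and the Mkx-CreER/flox columns (1, 4 and 5) were matched by genotype only, since their numbers differ from the replicate numbers of the labels. Symbols and positions came from GENCODE vM21 by Ensembl identifier, which paired 32158 identifiers with a symbol and left 127 without.

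Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr by genotype, libraries were scaled by TMM, and 1 quasi-likelihood model with robust dispersion was fitted to all 10 libraries with a term per genotype. Contrasts were Mkx-CreER/flox against the mean of both controls with equal weight, against each control alone, and Mkx-CreER/+ against Mkx-flox/+. Genes at a Benjamini-Hochberg adjusted p under 0.05 were called. CPM values are TMM-normalized. Total counts per library lay between 8680934 and 22656417, at which 3 counts correspond to 0.132 to 0.346 CPM, and such limits cover counting error only. Pairs of libraries of a genotype differed by 21.7 to 108 times what counting error gives (chi-square per degree of freedom), a spread that holds differences between mice, dissections and library preparations alike. The method was tested on simulated data with planted 2-fold and 4-fold changes in 5 simulations, which gave 9.2, 7.8 and 9.4 false calls per simulation for Mkx-CreER/flox against both controls, Mkx-CreER/+ and Mkx-flox/+. The simulations drew each gene on its own and planted changes only in genes with an average log2 CPM above 1. The recovery they gave may thus not hold in the real libraries. A planted list was called by camera and 0 of 20 random lists were.

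Before the data were examined, 32 gene lists and a rule for the genes to name were written down. Lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 between genes, adjusted over lists with at least 5 tested members. An estimated correlation and fry were the alternatives. The preset correlation is lower than many of the estimated ones, which reached 0.866 for mitochondrially encoded genes. List scores are the mean log2 CPM of a list's genes in a library. The lists are tendon transcription factors and markers, fibrillar and associated collagens, collagen folding with processing and cross-linking, proteoglycans and other tendon matrix, matrix-degrading enzymes and their inhibitors, cartilage, bone and mineralization, osteoclast, TGF-beta and BMP signalling, Wnt signalling, YAP/TAZ targets and mechanosensing, immediate-early genes, cell cycle, inflammatory mediators, interferon response, endoplasmic reticulum stress, glycolysis and hypoxia, nuclear-encoded oxidative phosphorylation, mitochondrially encoded, paratenon and sheath fibroblasts, senescence-associated, skeletal muscle, erythroid, macrophage, lymphocyte with neutrophil and mast cell, endothelial, mural and smooth muscle, Schwann cell and nerve, adipocyte, epidermis, nuclear-retained and small-nuclear RNA, and replication-dependent histones.

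Named genes were Mkx and, for the comparison with both controls, the 10 largest rises and 10 largest falls among called genes with an average log2 CPM of at least 1 whose Mkx-CreER/flox libraries all lay on 1 side of all 7 controls. For each comparison of single genotypes the rule took 5 and 5 in the same way, filled by smallest p where fewer passed. From each list it took up to 4 called members, or the 2 of smallest p where the list was called and no member passed. Predicted or numbered gene models, Y-linked genes and Xist were not named. By chance alone, groups of 3 and 3 do not overlap in 10% of genes and groups of 3 and 4 in 5.71%.

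Other settings fixed in advance were DESeq2 1.42.0, limma voom with sample quality weights, RLE and upper-quartile scaling, no filter, a stricter filter (CPM of at least 1 in 3 libraries), removal of mitochondrial, muscle and erythroid genes, the muscle list score as a covariate, only the groups compared, the 7 controls as 1 group, and each library left out in turn. Chosen after the data were seen were the muscle covariate with Mkx-CreER/flox 1 left out, the Schwann list score as a covariate, and the RLE and upper-quartile scalings for the list counts. Single values were compared by two-sided exact permutation tests. The counts of genes called were also set against other splits of the same libraries. A sex covariate was not run because all libraries had Y-linked transcripts and next to no Xist, and no block by replicate was possible.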

Results

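RNA was sequenced from the Achilles tendon of 10 mice of 3 genotypes, all given tamoxifen at 20 mg/kg at the age of 6 weeks and sampled 4 weeks later. Mkx encodes Mohawk, a homeobox transcription factor of tendon cells. The conditional knockout carried an Mkx-CreER allele, which makes a tamoxifen-activated Cre recombinase, and a floxed Mkx allele that Cre can delete (Mkx-CreER/flox, n = 3). The controls carried Mkx-CreER alone (Mkx-CreER/+, n = 3) or the floxed allele alone (Mkx-flox/+, n = 4). Libraries were made with RamDA-seq, a total RNA method for small inputs, and each value rests on counts per gene. The series text writes the floxed control as Mkx-flox, so the number of floxed copies in it is not settled here, and whether the CreER allele itself disrupts Mkx is not given in the sources used here. Both bear on how much Mkx each control holds. Library numbers here are the column numbers of the count table.

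Sequencing depth lay between 8680934 and 22656417 counts per library. The Mkx-CreER/+ libraries 1, 2 and 4 held 12801907, 19017142 and 22656417 counts, and the Mkx-CreER/flox libraries 1, 4 and 5 held 13185381, 18713250 and 12704595. The Mkx-flox/+ libraries 1 to 4 held 10357421, 8680934, 17792482 and 9044459 counts. After the filter on low counts, 16017 genes were tested.

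The tendon libraries also held RNA of skeletal muscle, in amounts that differed between genotypes. The 32 genes of the skeletal muscle list took 10.3% ± 2.57 (SD, n = 3) of the counts in Mkx-CreER/flox, 6.47% ± 2.69 (n = 3) in Mkx-CreER/+ and 3.79% ± 2.06 (n = 4) in Mkx-flox/+. Mitochondrially encoded transcripts took 6.04% ± 2.52, 3.42% ± 1.25 and 2.07% ± 0.172 of the counts in the same order. Library Mkx-CreER/flox 1 stood apart from the rest. It had the highest muscle share (13.2%), the highest mitochondrial share (8.85%) and the highest score on the first principal component (84.6, against -40.9 to 36.9 in the other 9 libraries), a component that held 29.9% of the variance.

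Mkx itself tests whether the genotypes behave as labelled. Mkx (ENSMUSG00000061013, chromosome 18, 6934518 to 7004780, minus strand, mm10) was lowest in every Mkx-CreER/flox library. It measured 29.7 ± 3.19 CPM (counts scaled to library size; mean ± SD, n = 3) there, 92.9 ± 1.30 in Mkx-CreER/+ (n = 3) and 159.7 ± 29.6 in Mkx-flox/+ (n = 4). Against both controls it fell by 2.04 on the log2 scale (SE 0.176, edgeR adjusted p = 0.000149), which left 24.4% of the control level. An exact permutation test on the 120 ways to pick 3 of the 10 libraries gave a two-sided p = 0.00833, the smallest it can give. Against Mkx-CreER/+ alone Mkx fell by 1.65 (SE 0.191, edgeR adjusted p = 0.00637), to 32.0% of that control. There the exact permutation p was 0.1, the smallest that 3 libraries against 3 allow. Against Mkx-flox/+ alone it fell by 2.43 (SE 0.189, edgeR adjusted p = 3.61e-05), to 18.6%, and the exact permutation p was 0.0286. The call against Mkx-CreER/+ ended with library Mkx-CreER/flox 4 left out (log2 fold change -1.72, edgeR adjusted p = 0.0549) and with only those groups in the fit (-1.66, adjusted p = 0.0575). Counts cover the whole gene, the deleted exons are not given in the sources used here, and reads from exons left in place would count toward the remainder.

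**Figure D1:**
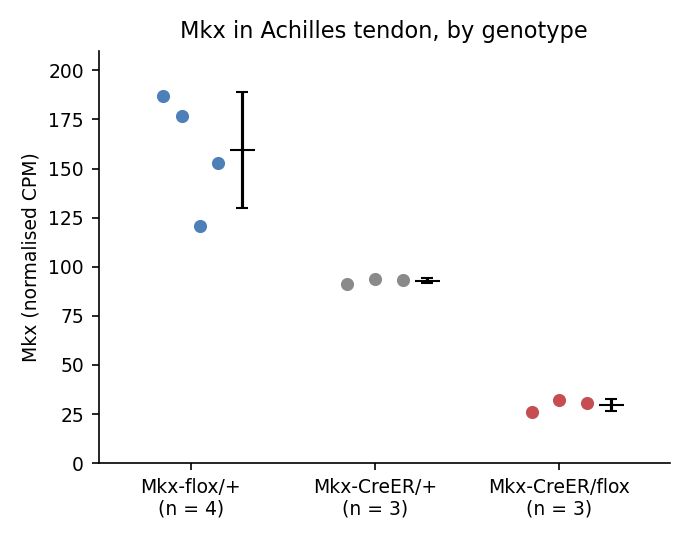
Mkx in normalized CPM, 1 point per library, by genotype, with the mean and SD of each group beside the points. The 3 Mkx-CreER/flox libraries lie between 26.1 and 32.4 CPM, the 3 Mkx-CreER/+ libraries between 91.4 and 93.8, and the 4 Mkx-flox/+ libraries between 121 and 187.

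The first comparison set Mkx-CreER/flox, in which Mkx was reduced, against both control genotypes with equal weight. Of the tendon matrix lists, 3 of 15 fibrillar collagens, 7 of 26 collagen folding genes and 8 of 30 proteoglycans and other matrix genes fell, and 2 of the 30 rose. The calls of these lists were lost with an estimated correlation (adjusted p of 0.262 to 0.452). Keratocan (Kera, ENSMUSG00000019932), a small leucine-rich proteoglycan, measured 103 ± 26.8 CPM in Mkx-CreER/flox (n = 3), 334 ± 83.5 in Mkx-CreER/+ (n = 3) and 517 ± 142 in Mkx-flox/+ (n = 4), a fall by 2.01 on the log2 scale (SE 0.264, adjusted p = 0.00467). The type I collagen chains Col1a1 and Col1a2 fell by 1.74 (SE 0.357) and 1.48 (SE 0.331). Macrophage genes fell as a group, among them the lysozyme gene Lyz2 by 1.38 (SE 0.285) and the complement genes C1qa by 1.63 and C1qb by 1.52, both named after their values were seen. Lists of mitochondrial, skeletal muscle, vessel wall and Schwann cell genes were higher, though no list was called with an estimated correlation, and the Schwann cell list was not higher in library Mkx-CreER/flox 1. Cdh19, a cadherin of Schwann cells, rose by 2.72 (SE 0.385, adjusted p = 0.00715).

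In edgeR, 744 genes changed at an adjusted p under 0.05, of which 485 rose and 259 fell, and 475 changed at least 2-fold. At an unadjusted p under 0.05 there were 3310. In simulated data of this design the test recovered 54.2% of planted 2-fold changes and 91.4% of planted 4-fold changes. The number of genes called moved with the library left out: 76 without Mkx-CreER/+ 1, 67 without Mkx-CreER/+ 2, 213 without Mkx-CreER/flox 1, 64 without Mkx-CreER/flox 4, and 246, 352 and 379 without Mkx-flox/+ 1, 2 and 3. It was 12 with the muscle score as a covariate, 1447 in DESeq2 and 2991 in limma voom. Of the 744 genes, 35 were called whichever library was left out, among them Mkx, Kera, Cdh19, Extl1, Sec14l5, Nmrk2, Ctnna3, Ms4a6b, Ttc9, Cpe, Ank3, Pla2g5, Rgs5, Tmem252 and Hk2. Each other gene named for this comparison as risen or fallen lost its call with at least 1 library left out. Of the genes named above as called in every omission, only Mkx, Kera, Cdh19, Ms4a6b and Pla2g5 kept their call with the muscle score as a covariate.

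Among genes whose 3 Mkx-CreER/flox libraries lay above or below all 7 controls, the largest rises besides Cdh19 were these. Fam81a rose by 2.81 (SE 0.539), Extl1, a glycosyltransferase of the exostosin family, by 2.38 (SE 0.319), and Lrrc55, an auxiliary subunit of potassium channels, by 2.36 (SE 0.589). Sec14l5 rose by 2.32 (SE 0.287), Nmrk2, a nicotinamide riboside kinase of muscle, by 2.29 (SE 0.333), and Ctnna3, an alpha-catenin of cardiac and other muscle, by 2.21 (SE 0.344). Rnf128, Efcab6 and Togaram2 rose by 2.20, 2.19 and 2.15, and Rnf128 stood at 1.174 (adjusted p = 0.306) without Mkx-CreER/flox 1. In Nmrk2, 14.6% of the exon length overlaps Atcayos on the other strand, and the strand setting of the counting is not given in the sources used here. The largest falls were Il31ra, a receptor subunit for interleukin-31, at -2.77 (SE 0.505) and Cnmd (chondromodulin), an angiogenesis inhibitor of cartilage, at -2.54 (SE 0.627). Vsig4 and Cd209b, receptors of tissue macrophages, stood at -2.19 (SE 0.451) and -2.12 (SE 0.524). Il31ra and Cd209b both measured 0.18 CPM in Mkx-CreER/flox 1, where 3 counts correspond to 0.228 CPM. Cnmd measured 0.15 CPM in Mkx-CreER/flox 5, where 3 counts correspond to 0.236 CPM. Ms4a6b, a membrane protein gene with close paralogs, fell by 1.96 (SE 0.293), Coch (cochlin) by 1.96 (SE 0.31), Phyhip by 1.95 (SE 0.444) and Krtdap, a keratinocyte gene, by 1.85 (SE 0.422).

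Tendon matrix lists were lower with the preset correlation of camera and were not called with an estimated one (adjusted p of 0.262 to 0.452), while the muscle share of the libraries was 10.3% in Mkx-CreER/flox against 6.47% and 3.79% in the controls. Of 26 genes for collagen folding, processing and cross-linking, 7 fell, 0 rose and 19 did not pass (14 fell and 1 rose adjusted over the list alone). Adamts2 and Pcolce, which act in the processing of procollagen ends, fell by 1.15 (SE 0.217) and 1.32 (SE 0.271). Crtap, part of the prolyl 3-hydroxylation complex, fell by 0.91 (SE 0.181) and Creb3l1, a transcription factor for collagen secretion, by 0.92 (SE 0.198). The list's median was -0.61 (camera adjusted p = 5.96e-08, with an estimated correlation p = 0.0413 and adjusted p = 0.3). Of 30 proteoglycans and other matrix genes, 8 fell and 2 rose (14 and 2 adjusted over the list alone), with a median of -0.59 (camera adjusted p = 1.57e-06, with an estimated correlation p = 0.0164 and adjusted p = 0.262). Besides Kera, the collagen-binding Fmod (fibromodulin) fell by 1.495 (SE 0.27) and Tgfbi by 1.29 (SE 0.21). The risen members were Aspn (asporin), a repressor of TGF-beta signalling, up by 1.12 (SE 0.228), and Postn (periostin), a matrix protein of repair, up by 1.46 (SE 0.317). Postn was named after its value was seen. Without Mkx-CreER/flox 1, Aspn stood at 0.608 (adjusted p = 0.086).

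Of 24 tendon transcription factors and markers, 7 fell and 1 rose (11 and 2 adjusted over the list alone), with a median of -0.61 (camera adjusted p = 3.07e-05, with an estimated correlation p = 0.0131 and adjusted p = 0.262). Mkx, Kera, Fmod and the Wnt inhibitor Wif1 (-1.23, SE 0.215) were among those that fell. Scx (scleraxis) and Tnmd (tenomodulin), markers of tendon cells named here after their values were seen, did not pass, at -0.38 (SE 0.299, adjusted p = 0.52) and -0.70 (SE 0.314, adjusted p = 0.228). Of 15 fibrillar and associated collagens, Col1a1, Col1a2 and Col16a1 fell (-1.21, SE 0.216, for Col16a1) and 12 did not pass (6 fell and 2 rose adjusted over the list alone). The median was -0.37 (camera adjusted p = 0.00756, p = 0.231 with an estimated correlation). Matrix-degrading enzymes and their inhibitors had a median of -0.26 (camera adjusted p = 0.0303, p = 0.114 with an estimated correlation). Of 25 members 3 fell (8 fell and 2 rose adjusted over the list alone), namely Mmp23 by 1.45, the collagenolytic cathepsin Ctsk by 1.02 and Timp2 by 0.99. That call ended without Mkx-CreER/flox 5 (adjusted p = 0.193) or Mkx-flox/+ 4 (0.0567), and the mean went from -0.202 to -0.371 without Mkx-CreER/flox 4.

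Macrophage genes fell most uniformly. Of 23 members, 17 fell, 0 rose and 6 did not pass (22 fell adjusted over the list alone), and all 23 had negative fold changes, with a median of -1.08 (camera adjusted p = 4.81e-16, with an estimated correlation p = 0.0413 and adjusted p = 0.3). Csf1r, the receptor for colony-stimulating factor, fell by 1.37 (SE 0.261), Tyrobp by 1.31 (SE 0.26), the Fc receptor Fcgr3 by 1.24 (SE 0.253), and Lyz2 measured 358 ± 17.4 CPM against 936.5 ± 438 in Mkx-CreER/+ and 932 ± 216 in Mkx-flox/+. In Csf1r, 15.1% of the exon length overlaps Hmgxb3 on the other strand. The mean log2 CPM of the list was 4.96 ± 0.024 in Mkx-CreER/flox (n = 3), 6.01 ± 0.587 in Mkx-CreER/+ (n = 3) and 6.08 ± 0.275 in Mkx-flox/+ (n = 4). Library Mkx-CreER/+ 4, at 5.35, was the control nearest to the Mkx-CreER/flox range.

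Lists of inflammatory, interferon response and paratenon genes had lower medians, with few members passing and no call with an estimated correlation (adjusted p of 0.346 to 0.407). The list of lymphocyte, neutrophil and mast cell genes was not called (0.244). Of 27 inflammatory mediators, complement C3 (-1.12, SE 0.24), Lcn2 (-1.22, SE 0.291) and Nfkbia (-0.82, SE 0.22) fell and 24 did not pass, and 3 fell adjusted over the list alone. The median was -0.26 (camera adjusted p = 0.0304, p = 0.138 with an estimated correlation), and the call ended without Mkx-CreER/+ 1 (0.0815), Mkx-CreER/flox 1 (0.0592) or Mkx-CreER/flox 5 (0.125). None of the 23 interferon response genes passed, over all genes or over the list alone. Their median was -0.28 (camera adjusted p = 0.00292, p = 0.178 with an estimated correlation; adjusted p = 0.103 without Mkx-CreER/flox 5), with Ifi27l2a at -1.13 and Oas1a at -1.44. Their mean went from -0.386 to -0.642 without Mkx-CreER/flox 4. Of 20 paratenon and sheath fibroblast genes Ly6c1 fell by 0.83 (SE 0.197), 3 fell adjusted over the list alone, and the median was -0.38 (camera adjusted p = 0.000174, p = 0.0933 with an estimated correlation). Against Mkx-flox/+ alone the inflammatory (camera adjusted p = 0.254) and interferon response (0.354) lists were not called, while the paratenon list was (0.00242). Inflammatory and interferon response lists were also higher in Mkx-CreER/+ than in Mkx-flox/+ with the preset correlation.

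Mitochondrial and skeletal muscle lists were higher in Mkx-CreER/flox, and most so in library 1. Of 9 mitochondrially encoded transcripts 6 rose, 0 fell and 3 did not pass (8 rose adjusted over the list alone), with a median of 1.22 (camera adjusted p = 1.44e-06, p = 0.0974 with an estimated correlation). The respiratory chain subunits mt-Nd2 and mt-Co1 rose by 1.501 (SE 0.316) and 1.37 (SE 0.313), and mt-Nd5 and mt-Nd4 by 1.19 and 1.13. Of 37 nuclear genes of oxidative phosphorylation 3 rose, 0 fell and 34 did not pass, with a median of 0.68 (camera adjusted p = 4.98e-08, p = 0.24 with an estimated correlation). Adjusted over the list alone, 25 rose and 1 fell. Cytochrome c (Cycs) rose by 1.03 (SE 0.25), and the complex I genes Ndufs1 and Ndufb5 by 1.07 (SE 0.26) and 1.20 (SE 0.307). Of 32 skeletal muscle genes 6 rose, 0 fell and 26 did not pass (14 rose adjusted over the list alone), with a median of 0.67 (camera adjusted p = 8.93e-07, p = 0.164 with an estimated correlation). Myoglobin (Mb) rose by 1.94 (SE 0.372), the myosin chain Myh2 by 1.61 (SE 0.383), beta-tropomyosin (Tpm2) by 1.29 (SE 0.305) and telethonin (Tcap) by 1.27 (SE 0.263). Without Mkx-CreER/flox 1 the list means went from 0.68 to 0.183 for oxidative phosphorylation, from 1.261 to 0.795 for mitochondrially encoded genes and from 0.789 to 0.399 for skeletal muscle, all still called. Ndufb5 then stood at 0.422 and Ndufs1 at 0.529, mt-Nd2 at 0.956, mt-Co1 at 0.785, mt-Nd5 at 0.754, mt-Nd4 at 0.593 and Tpm2 at 0.811, none of which passed (adjusted p of 0.111 to 0.286). The oxidative phosphorylation score of Mkx-CreER/flox 5 (6.691) lay below those of the 3 Mkx-CreER/+ libraries (6.763 to 6.996). Without Mkx-CreER/flox 1 and with the muscle score as a covariate, the oxidative phosphorylation mean was 0.099 and its call ended (adjusted p = 0.329). Genes on the other strand overlap 27.6% of the exon length of Mb and 12.3% of that of Ndufb5.

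Vessel and nerve lists were higher as well, though not in every Mkx-CreER/flox library. Of 16 mural and smooth muscle genes, the pericyte marker Rgs5 (1.26, SE 0.199), the potassium channel subunit Abcc9 (1.19, SE 0.24) and desmin (Des, 1.29, SE 0.303) rose and 13 did not pass (7 rose adjusted over the list alone). The list's median was 0.87 (camera adjusted p = 7.45e-05, p = 0.0567 with an estimated correlation). Rgs5, Abcc9 and Des were highest in Mkx-CreER/flox 1 (654, 229 and 817 CPM), the library with the highest muscle share. None of them kept its call with the muscle score as a covariate. In Mkx-flox/+ 1 to 4, Des measured 131, 143, 272 and 396 CPM, in the order of the muscle shares (1.87%, 2.15%, 5.37% and 5.75%). With the Schwann list score as a covariate the mural mean went from 1.024 to 0.362 (adjusted p = 0.129) and the endothelial mean from 0.361 to 0.2 (adjusted p = 0.129), and both calls ended. Of 20 endothelial genes 4 rose (5 adjusted over the list alone), with a median of 0.38 (camera adjusted p = 0.000964, p = 0.0846 with an estimated correlation; 0.0633 adjusted without Mkx-CreER/flox 5). They were Prox1, a lymphatic endothelial regulator (1.24, SE 0.257), the VEGF receptors Kdr (0.72, SE 0.158) and Flt1 (0.67, SE 0.151), and Ptprb (0.63, SE 0.155). Prox1, Kdr and Flt1 were also highest in Mkx-CreER/flox 1 (50.1, 109 and 81.4 CPM), while Ptprb was lower there than in the other Mkx-CreER/flox libraries. Of 16 Schwann cell and nerve genes Cdh19 and Drp2 (2.05, SE 0.405) rose, 9 rose adjusted over the list alone, and the median was 2.29 (camera adjusted p = 9.09e-05, p = 0.222 with an estimated correlation; list mean 1.264 against 2.055 and adjusted p = 0.0565 without Mkx-CreER/flox 5). The list score was 1.156, 4.304 and 5.171 in Mkx-CreER/flox 1, 4 and 5, against 1.162 to 3.519 in the 7 controls, so library 1 was the lowest of all 10. The mural score of library 1 (4.411) lay within the control range (3.751 to 4.887). Drp2 measured 38.0, 121 and 212 CPM in Mkx-CreER/flox 1, 4 and 5, against 19.7 to 45.5 CPM in the 7 controls.

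In all, camera called 18 of the 32 lists, 6 up and 12 down, and 11 without Mkx-CreER/flox 5. With an estimated correlation it called 0 (smallest adjusted p = 0.262), with an unadjusted p under 0.05 for 5 lists. The fry test called 5. Besides the lists above, osteoclast genes (7 members, 1 fell over all genes and over the list alone, namely Ctsk; median -0.18, camera adjusted p = 0.0314), adipocyte genes (21 members, 0 passed either way; median -0.37, adjusted p = 0.0334) and senescence-associated genes (14 members, 2 fell; 4 fell and 1 rose adjusted over the list alone; median -0.19, adjusted p = 0.0417) were called down. With an estimated correlation their p-values were 0.143, 0.433 and 0.0468, and the last was 0.3 adjusted. Against Mkx-flox/+ alone none of them was called (camera adjusted p = 0.0713, 0.717 and 0.0713). The fallen senescence-associated members were Igfbp3 (-0.93) and Igfbp4 (-0.96), which bind insulin-like growth factors. Among adipocyte genes Slc2a4, the insulin-responsive glucose transporter, stood at 0.78 and Retn (resistin) at -1.09. The osteoclast call ended without Mkx-CreER/+ 1 (0.0643), Mkx-CreER/flox 1 (0.254) or 5 (0.056) or Mkx-flox/+ 4 (0.0531), and the adipocyte call without Mkx-CreER/+ 1 (0.0973), Mkx-CreER/flox 1 (0.155) or 5 (0.711) or Mkx-flox/+ 3 (0.0756) or 4 (0.0531). Without Mkx-CreER/flox 4 the osteoclast mean went from -0.303 to -1.14 and the adipocyte mean from -0.301 to -0.617, and the osteoclast mean was -0.101 without Mkx-CreER/flox 1 and the adipocyte mean -0.147 without Mkx-CreER/flox 5. With the muscle covariate the osteoclast (0.115), adipocyte (0.0834) and senescence (0.0974) calls ended. The senescence call also ended without Mkx-CreER/+ 1 (0.0511), Mkx-CreER/flox 1 (0.0517), 4 (0.0532) or 5 (0.12) or Mkx-flox/+ 1 (0.0588), 3 (0.0588) or 4 (0.0531).

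The other 14 lists were not called in this comparison. Camera adjusted p-values were 0.143 for bone and mineralization, 0.184 for TGF-beta and BMP signalling, for Wnt signalling and for replication-dependent histones, 0.244 for lymphocytes, neutrophils and mast cells, 0.278 for immediate-early genes and 0.339 for epidermis. They were 0.528 for YAP/TAZ targets and mechanosensing, 0.651 for erythroid genes, 0.685 for the cell cycle, for nuclear RNA and for endoplasmic reticulum stress, 0.933 for glycolysis and hypoxia and 0.969 for cartilage. Single members passed in some of them. Ankrd1 (1.66, SE 0.3) and Tead1 (0.82, SE 0.194), both of the YAP/TAZ list, rose (Tead1 0.528 without Mkx-CreER/flox 1), as did the glycolytic enzyme Hk2 (1.32, SE 0.223), the Wnt antagonist Frzb (1.31, SE 0.282) and the transferrin receptor Tfrc (1.80, SE 0.398). The BMP antagonist Chrd (-0.66, SE 0.157), Dkk3 (-0.75, SE 0.179), the cartilage collagen Col11a2 (-1.73, SE 0.366), Angptl4 (-1.04, SE 0.222) and the imprinted noncoding RNA Meg3 (-0.68, SE 0.164) fell. Adjusted over the list alone, the counts were 2 for YAP/TAZ, 5 for glycolysis, 3 for cartilage, 3 for erythroid genes, 1 each for TGF-beta, Wnt, epidermis and nuclear RNA, and 0 for the other 6. The erythroid median was -0.59 while the mean was 0.13, and for nuclear RNA the median was 0.14 and the mean -0.19. The median and mean were also opposite in sign for glycolysis and hypoxia, at -0.017 and 0.019.

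**Figure D2:**
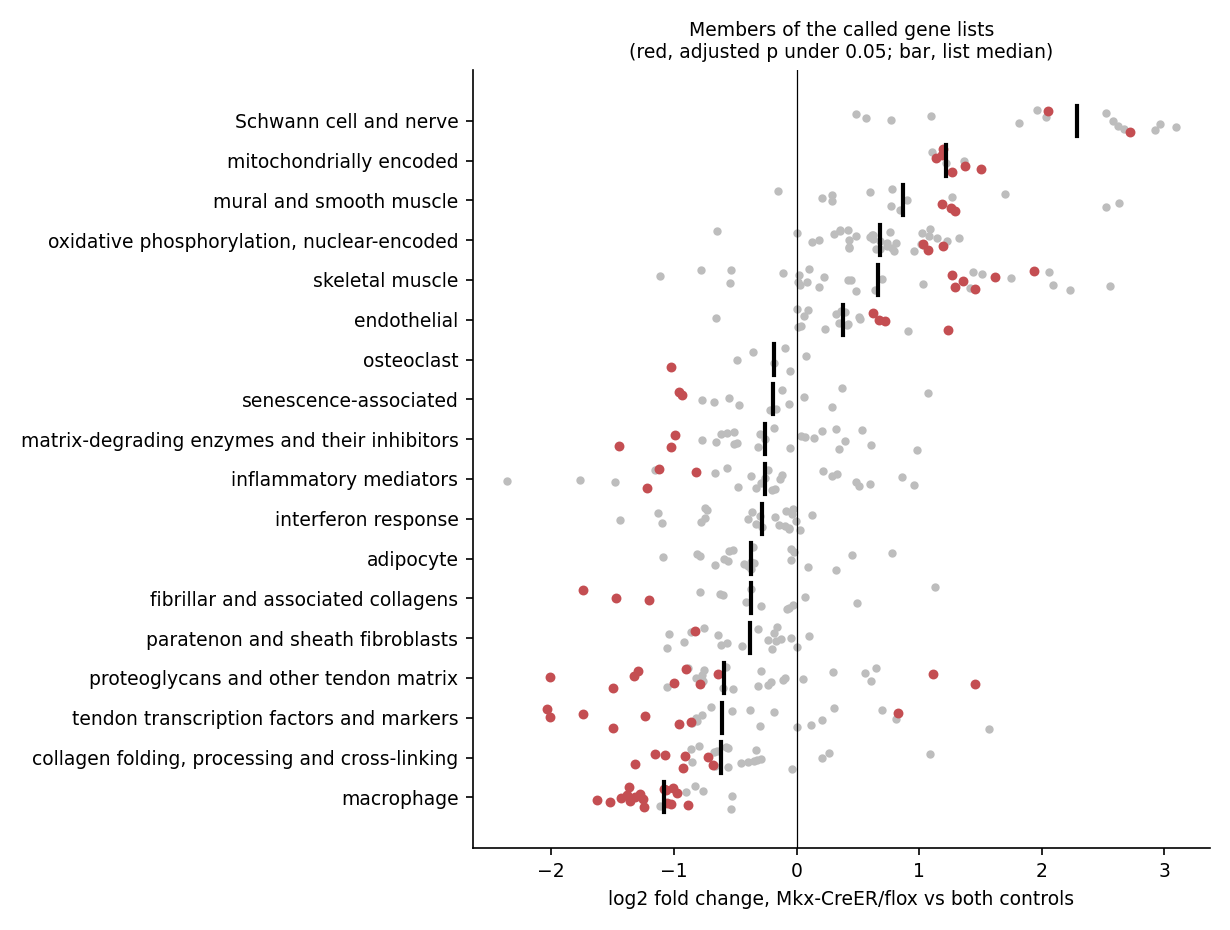
Log2 fold changes of single genes in Mkx-CreER/flox (n = 3) against both controls (n = 3 and n = 4), 1 point per gene, for the 18 lists called by camera. Red points passed an adjusted p under 0.05 over all genes and black bars are list medians, which run from -1.08 for macrophage genes to 2.29 for Schwann cell and nerve genes.

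The second comparison set Mkx-CreER/flox against the control that shares its CreER allele. Mkx was lower in Mkx-CreER/flox than in Mkx-CreER/+. Macrophage and interferon response lists were lower with the preset correlation of camera and were not called with an estimated one (adjusted p = 0.253 for both). All 23 macrophage genes had negative fold changes with a median of -1.16 (camera adjusted p = 1.35e-18, with an estimated correlation p = 0.0312 and adjusted p = 0.253). Kera had a log2 fold change of -1.70 (SE 0.287), the antimicrobial oxidase gene Cybb -1.13 (SE 0.229) and Cdh19 2.52 (SE 0.497), none of which passed after adjustment (0.178, 0.237 and 0.237).

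In edgeR, 1 gene passed, Mkx, and 1720 genes had an unadjusted p under 0.05. The test recovered 34.2% of planted 2-fold and 86.6% of planted 4-fold changes in simulated data. A call was thus possible with 3 libraries against 3 under the simulated spread. The simulations drew each gene on its own, so these shares may not hold in the real libraries, where genes vary together. Genes next by p did not pass. They were Ttc9 at 1.68 (SE 0.313), the spectrin-binding adaptor Ank3 at 0.92 (SE 0.176), Sec14l5 at 1.86 (SE 0.362), Cdh19, and the prohormone carboxypeptidase Cpe at 0.91 (SE 0.184) on the higher side. On the lower side were Kera, Ms4a6b at -1.89 (SE 0.321), Coch at -1.85 (SE 0.339) and Cybb, with edgeR adjusted p-values of 0.178 to 0.237 for all 9. The number called was 117 without Mkx-CreER/+ 4, 6 without Mkx-CreER/flox 1, 2 without Mkx-CreER/+ 2, 0 without Mkx-CreER/flox 4 and 0 with only these groups in the fit. It was 123 in DESeq2, 715 in limma voom and 9 with no filter on low counts.

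Camera called 15 of the 32 lists, 6 up and 9 down, though 0 passed with an estimated correlation (smallest adjusted p = 0.253, unadjusted p under 0.05 for 5 lists). The fry test called 0 of these 15. It called only the senescence-associated list (fry adjusted p = 0.048), which camera did not call (adjusted p = 0.053). Adjusted over the list alone, 21 of 23 macrophage genes fell, against 0 over all genes. Interferon response genes had a median of -0.58 (camera adjusted p = 5.02e-07, with an estimated correlation p = 0.0388 and adjusted p = 0.253), and 3 of 23 fell adjusted over the list alone. Inflammatory mediators had a median of -0.36 (adjusted p = 0.000761, estimated-correlation p = 0.0432 and adjusted p = 0.253, 3 of 27 fell over the list alone) and paratenon genes one of -0.40 (adjusted p = 5.24e-05, estimated-correlation p = 0.0639, 2 of 20). Adipocyte genes had a median of -0.54 (adjusted p = 8.09e-05, estimated-correlation p = 0.166, 0 of 21) and osteoclast genes one of -0.28 (adjusted p = 0.0301, estimated-correlation p = 0.134, 0 of 7). Tendon transcription factors and markers stood at -0.38 (adjusted p = 0.000403, estimated-correlation p = 0.0261 and adjusted p = 0.253, 5 fell and 1 rose of 24), proteoglycans at -0.33 (adjusted p = 0.000179, estimated-correlation p = 0.042 and adjusted p = 0.253, 3 of 30 fell) and collagen folding at -0.30 (adjusted p = 0.000622, estimated-correlation p = 0.159, 0 of 26). Fibrillar collagens were not called (median -0.06, adjusted p = 0.228). Without Mkx-CreER/flox 4 the mean of tendon factors and markers went from -0.316 to -0.197, of osteoclast genes from -0.298 to -1.135 and of adipocyte genes from -0.544 to -0.861. Without Mkx-CreER/flox 5 the mean of collagen folding went from -0.248 to -0.382 and of proteoglycans from -0.26 to -0.401.

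Mural genes had a median of 0.92 (adjusted p = 8.09e-05, estimated-correlation p = 0.0554, 2 of 16 rose over the list alone) and Schwann cell genes one of 1.91 (adjusted p = 0.000112, estimated-correlation p = 0.224, 2 of 16). Mitochondrially encoded genes stood at 0.93 (adjusted p = 8.09e-05, estimated-correlation p = 0.154, 7 of 9), oxidative phosphorylation at 0.50 (adjusted p = 8.09e-05, estimated-correlation p = 0.383, 0 of 37), skeletal muscle at 0.40 (adjusted p = 0.000428, estimated-correlation p = 0.303, 0 of 32) and endothelial genes at 0.23 (adjusted p = 0.0301, estimated-correlation p = 0.212, 0 of 20). The muscle share was 10.3% against 6.47%. Without Mkx-CreER/flox 1 the oxidative phosphorylation mean was -0.001 (adjusted p = 0.886) the skeletal muscle mean 0.08 (0.0901) and the mitochondrially encoded mean 0.419. The skeletal muscle mean was 0.467 with all libraries, 0.21 without Mkx-CreER/+ 1 and 1.112 without Mkx-CreER/+ 2. Without Mkx-CreER/+ 1 the mural mean went from 0.862 to 1.366 and the Schwann cell mean from 1.764 to 3.068. Without Mkx-CreER/flox 5 the calls for Schwann cell (mean 1.764 to 0.974, adjusted p = 0.0698), endothelial (0.22 to 0.099, 0.322) and adipocyte genes (-0.544 to -0.39, 0.0587) ended. The endothelial call also ended without Mkx-CreER/+ 4 (0.145, 0.232), and the osteoclast call without Mkx-CreER/+ 1 (-0.122, 0.117) or Mkx-CreER/flox 1 (-0.096, 0.258). With the muscle covariate the oxidative phosphorylation (0.0932), endothelial (0.14) and osteoclast (0.0846) calls ended, and with the Schwann covariate the mural (mean 0.324, 0.104) and endothelial (0.067, 0.527) calls.

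The third comparison set Mkx-CreER/flox against the control that carries the floxed allele without CreER. In edgeR 6 of 15 fibrillar collagens and 13 of 26 collagen folding genes fell in Mkx-CreER/flox against Mkx-flox/+, and 11 of 32 skeletal muscle genes and 8 of 9 mitochondrially encoded genes rose. Their list calls were lost with an estimated correlation (smallest adjusted p of any list 0.186). Col1a1 fell by 2.57 (SE 0.392, adjusted p = 0.00384), from 24280 ± 11100 CPM (SD, n = 4) to 4086 ± 941 (n = 3), and Col1a2 fell by 2.12 (SE 0.362). Fmod fell by 1.98 (SE 0.294) and Kera by 2.33 (SE 0.283). Mb rose by 2.53 (SE 0.441) and Myh2 by 2.11 (SE 0.448), with a muscle share of 10.3% against 3.79%.

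In edgeR, 1165 genes passed, of which 700 rose and 465 fell, 806 by at least 2-fold, with 3690 at an unadjusted p under 0.05. In simulated data of the same design 42.2% of planted 2-fold changes and 89.0% of planted 4-fold changes were recovered. The largest rises among genes with no overlap between the groups were Sorcs1, a sorting receptor of neurons, by 5.25 (SE 1.01), Fam81a by 3.75 (SE 0.686) and the ketone body enzyme Bdh1 by 3.70 (SE 0.808). Shisa3 and Csrp3, the muscle LIM protein, followed at 3.06 (SE 0.549) and 3.04 (SE 0.749). Sorcs1 measured 1.09, 7.22 and 21.8 CPM in Mkx-CreER/flox 1, 4 and 5, and at most 0.72 in the Mkx-flox/+ libraries. The largest falls were Klk1b21, a kallikrein with close paralogs, by 4.58 (SE 1.07), Il31ra by 3.28 (SE 0.535), Cnmd by 3.15 (SE 0.667), Gpha2, a glycoprotein hormone subunit, by 2.85 (SE 0.653) and Phyhip by 2.63 (SE 0.477). The sizes of some of these falls rest on a few counts. Klk1b21 and Il31ra measured 0.09 and 0.18 CPM in Mkx-CreER/flox 1, where 3 counts correspond to 0.228 CPM. Klk1b21 and Cnmd measured 0.07 and 0.15 CPM in Mkx-CreER/flox 5, where 3 counts correspond to 0.236 CPM. Of the 1165 genes, 277 were called whichever library was left out. The calls of Klk1b21 and Bdh1 ended in 5 of the 10 omissions, that of Csrp3 in 6, Gpha2 in 3 and Cnmd in 1, and those of Sorcs1, Fam81a, Shisa3, Il31ra and Phyhip in 0. The number called was 632 without Mkx-CreER/flox 1, 518 without Mkx-CreER/flox 4, and 455, 640 and 546 without Mkx-flox/+ 1, 2 and 3. It was 41 with the muscle score as a covariate, 1830 in DESeq2 and 2853 in limma voom. With the covariate the median of the 465 fallen genes went from -1.074 (SE 0.243) to -1.088 (SE 0.314). That of the 700 risen genes went from 1.364 (SE 0.305) to 1.003 (SE 0.387).

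Camera called 13 lists, 6 up and 7 down, though 0 with an estimated correlation (smallest adjusted p = 0.186, unadjusted p under 0.05 for 3 lists). The fry test called 10 lists, of which 9 were among these 13. Of 26 collagen folding genes 13 fell (20 fell and 2 rose adjusted over the list alone), with a median of -0.86 (camera adjusted p = 1.77e-10, with an estimated correlation p = 0.0228 and adjusted p = 0.243). Of 30 proteoglycans and other matrix genes 12 fell and 2 rose (17 and 2 over the list alone; median -0.82, adjusted p = 2.07e-07, estimated-correlation p = 0.0116 and adjusted p = 0.186). Of 24 tendon factors and markers 10 fell and 2 rose (14 and 2 over the list alone; median -1.01, adjusted p = 9.16e-06, estimated-correlation p = 0.0102 and adjusted p = 0.186). Of 15 fibrillar collagens 6 fell (7 fell and 2 rose over the list alone; median -0.54, adjusted p = 0.000523, estimated-correlation p = 0.141). Of 25 matrix-degrading enzymes 7 fell (7 fell and 2 rose over the list alone; median -0.29, adjusted p = 0.0234, estimated-correlation p = 0.101), and that call ended without Mkx-CreER/flox 5 (0.155) or Mkx-flox/+ 4 (0.0801), and the mean went from -0.287 to -0.455 without Mkx-CreER/flox 4. Of 23 macrophage genes 16 fell (21 over the list alone; median -1.20, adjusted p = 7.01e-13, estimated-correlation p = 0.0606), and of 20 paratenon genes 2 fell (2; median -0.36, adjusted p = 0.00242, estimated-correlation p = 0.155).

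Of 37 oxidative phosphorylation genes 11 rose (31 rose and 1 fell over the list alone; median 0.85, adjusted p = 4.12e-10, estimated-correlation p = 0.195). Of 9 mitochondrially encoded genes 8 rose (9 over the list alone; median 1.58, adjusted p = 3.15e-07, estimated-correlation p = 0.0853), and of 32 skeletal muscle genes 11 rose (14; median 0.93, adjusted p = 1.71e-08, estimated-correlation p = 0.123). Of 20 endothelial genes 5 rose (6 over the list alone; median 0.53, adjusted p = 0.000138, estimated-correlation p = 0.0537), of 16 mural genes 3 (7; median 1.05, adjusted p = 0.000281, estimated-correlation p = 0.0751) and of 16 Schwann cell genes 2 (8; median 2.42, adjusted p = 0.000281, estimated-correlation p = 0.251). Without Mkx-CreER/flox 5 the Schwann cell mean went from 2.347 to 1.554 (adjusted p = 0.0501), and with the Schwann covariate the mural mean went from 1.185 to 0.4 (0.166). Without Mkx-CreER/flox 1 the mean went from 0.865 to 0.368 for oxidative phosphorylation and from 1.111 to 0.718 for skeletal muscle, both still called. Interferon response genes were not called here (median -0.08, adjusted p = 0.354). Nor were inflammatory mediators (median -0.23, adjusted p = 0.254) or adipocyte genes (median -0.12, adjusted p = 0.717).

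**Figure D3:**
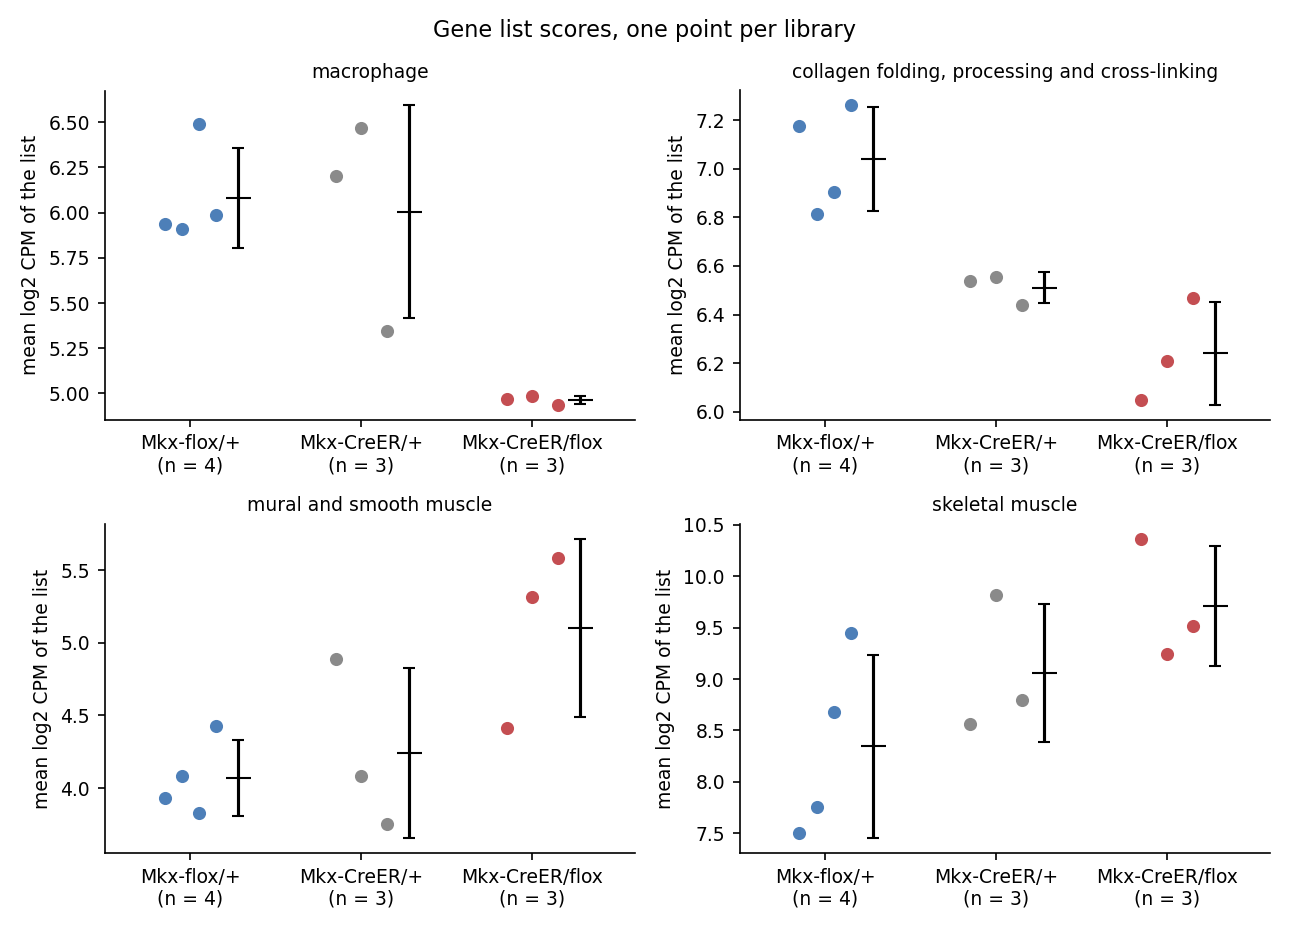
Mean log2 CPM of the genes of 4 lists, 1 point per library, with the mean and SD of each genotype. The 3 Mkx-CreER/flox libraries lie between 4.94 and 4.98 on the macrophage list, below all 7 controls (5.35 to 6.49), and the libraries of the genotypes overlap on the skeletal muscle list.

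Genes that moved the same way against each control were counted next, to find changes that do not rest on the choice of control. Mkx was the only gene called in edgeR against each of them, and 0.05 such genes were seen on average in 20 simulations of unchanged groups that shared the Mkx-CreER/flox libraries. At an unadjusted p under 0.05, 1402 genes moved the same way against each control, where the simulations gave 170.4 on average. Independent lists of these sizes would share 117.4 risen and 82.25 fallen genes. The simulations drew each gene on its own, while genes of these libraries vary together (estimated correlations within lists up to 0.866). Overlap without an effect of genotype may thus be larger than 170.4. Of the 744 genes called against both controls together, 695 had an unadjusted p under 0.05 against each. That contrast is the mean of the single ones in the same fit, so this number was largely set by the selection and adds no support. The count called against each was 118 in DESeq2, 644 in limma voom, 108 without Mkx-CreER/+ 4, 6 without Mkx-CreER/flox 1, 2 without Mkx-CreER/+ 2 and 0 without Mkx-CreER/flox 4.

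The last comparison set the control genotypes against each other. Lists of collagens and their processing enzymes were lower in Mkx-CreER/+ than in Mkx-flox/+ with the preset correlation of camera, and muscle, mitochondrial, interferon response and adipocyte lists were higher. None of the lists was called with an estimated correlation (smallest adjusted p = 0.148), and the skeletal muscle mean was -0.003 without Mkx-CreER/+ 2. No single gene passed in edgeR, and DESeq2 called 34. Mkx had a log2 fold change of -0.78 (SE 0.176, edgeR unadjusted p = 0.000499, adjusted p = 0.489), or 58.2% of the level in Mkx-flox/+. Its exact permutation p was 0.0571 over 35 splits, where the smallest possible is 0.0286. Col1a1 stood at -1.66 (SE 0.376, adjusted p = 0.489) and Creb3l1 at -1.05 (SE 0.214, adjusted p = 0.489).

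In edgeR 0 genes passed, 798 had an unadjusted p under 0.05, DESeq2 called 34 and limma voom 0. The genes of smallest p, none of which passed (adjusted p-values of 0.489 to 0.524), were Tmem252 at 1.31 (SE 0.274), Hk2 at 1.17 (SE 0.256), Tcap at 1.31 (SE 0.301), Zfp366, a corepressor of dendritic cells, at 1.21 (SE 0.281) and the opioid precursor Penk at 1.10 (SE 0.26). On the lower side were the phospholipase Pla2g5 at -1.01 (SE 0.182), Meg3 at -0.91 (SE 0.178), the cystine transporter Slc7a11 at -1.86 (SE 0.378), Creb3l1, and Flrt1 at -1.41 (SE 0.301). With 1 library left out Tmem252 ranged from 0.841 to 1.495. Camera called 13 lists, 8 up and 5 down (20 without Mkx-CreER/+ 4), 0 with an estimated correlation (smallest adjusted p = 0.148, unadjusted p under 0.05 for 3 lists) and 0 with fry.

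Of 26 collagen folding genes 0 fell over all genes and 11 over the list alone, with a median of -0.54 (camera adjusted p = 1.46e-13, with an estimated correlation p = 0.0122 and adjusted p = 0.148). Proteoglycans stood at -0.42 (adjusted p = 8.15e-07, estimated-correlation p = 0.0138 and adjusted p = 0.148, 0 of 30 over the list alone), fibrillar collagens at -0.50 (adjusted p = 1.81e-06, estimated-correlation p = 0.0582, 6 of 15 fell) and tendon factors and markers at -0.30 (adjusted p = 1.57e-05, estimated-correlation p = 0.0117 and adjusted p = 0.148, 6 of 24 fell). The cartilage list had a median of -0.07 and a mean of -0.38 (adjusted p = 0.00993, estimated-correlation p = 0.102, 3 of 19 fell). Skeletal muscle stood at 0.61 (adjusted p = 7.03e-08, estimated-correlation p = 0.133, 1 of 32 rose), oxidative phosphorylation at 0.39 (adjusted p = 7.03e-08, estimated-correlation p = 0.247, 0 of 37) and mitochondrially encoded genes at 0.67 (adjusted p = 5.37e-05, estimated-correlation p = 0.154, 0 of 9), with a muscle share of 6.47% against 3.79%. Adipocyte genes had a median of 0.51 (adjusted p = 1.81e-06, estimated-correlation p = 0.118, 0 of 21), interferon response genes 0.53 (adjusted p = 1.81e-06, estimated-correlation p = 0.0517, 0 of 23), endothelial genes 0.32 (adjusted p = 0.000112, estimated-correlation p = 0.0538, 0 of 20), inflammatory mediators 0.29 (adjusted p = 0.035, estimated-correlation p = 0.134, 0 of 27) and erythroid genes 0.55 (adjusted p = 0.0488, estimated-correlation p = 0.188, 0 of 7). The macrophage list was not called (median -0.002, adjusted p = 0.47). Without Mkx-CreER/+ 4 the mitochondrially encoded mean went from 0.772 to 0.357, and without Mkx-flox/+ 4 the fibrillar collagen mean went from -0.487 to -0.302. The skeletal muscle mean was 0.643 with all libraries, 0.423 without Mkx-flox/+ 1 and 1.025 without Mkx-flox/+ 4. Without Mkx-CreER/+ 2 the skeletal muscle mean was -0.003, and the cartilage (0.169), inflammatory (0.0911) and erythroid (0.585) calls ended. The inflammatory call also ended without Mkx-CreER/+ 1 (0.327) or Mkx-flox/+ 1 (0.0566), 2 (0.216) or 4 (0.0577), the cartilage call without Mkx-flox/+ 1 (0.0566), and the erythroid call without Mkx-CreER/flox 1 (0.0618) or Mkx-flox/+ 1, 2 or 3 (0.0942, 0.141 and 0.109).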

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

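The tests of a smaller share of tendon cells and of library Mkx-CreER/flox 1 as the source of the macrophage change were chosen only after the results were seen. Of 130 values tested in the 4 Mkx-flox/+ libraries, 7 (5.38%) had 1 library far from the other 3, where chance gives about 1 in 20. In Mkx-flox/+ 3, Vsig4 measured 19.61 CPM (others 5.79 to 6.83), Ankrd1 5.51 (11.75 to 12.46), Lcn2 44.1 (16.42 to 20.44), Fcgr3 73.6 (51.9 to 55.09) and the macrophage score 6.489 (5.907 to 5.989). Igfbp4 measured 225.01 CPM in Mkx-flox/+ 2 (350.27 to 360.51) and Tpm2 969.05 in Mkx-flox/+ 4 (384.14 to 480.62).

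The matrix lists were lower in Mkx-CreER/flox: the mean of 71 genes changed by -0.471 (SE 0.105). Muscle RNA that dilutes tendon RNA might lower them, but the slope on the muscle score within the controls predicted a change of 0.06 (SE 0.08), which differed from the observed one by -0.53 (SE 0.131). A smaller share of tendon cells would raise the genes of every other cell type alike. Mural and macrophage scores moved apart by 2.025 (SE 0.375), though the mural list mean fell to 0.362 (not called) with the Schwann score as a covariate. The opposite directions were known when this test was chosen. A smaller tendon share along with fewer macrophages would give the same gap, so the gap does not decide on that cause. The slope argues against muscle RNA as the whole cause. A smaller share of tendon cells, an effect of Mkx loss on them and a change in how the tendon was dissected stay open. So does the CreER allele, whose own comparison also gave lower matrix lists, though none was called with an estimated correlation (smallest adjusted p = 0.148).

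The macrophage list was lower by 1.079 (SE 0.251, 23 genes). The slope on the muscle score predicted a change of 0.21 (SE 0.244), and without library Mkx-CreER/flox 1 the change was 1.003 times as large (-1.082, SE 0.314). Both argue against muscle RNA or that library as the whole cause. Fewer macrophages and lower expression in each macrophage may each give this pattern, and bulk RNA does not part them. A change in how the tendon was dissected, left open for the matrix lists, stays open here too. The paratenon and sheath score was also lower, at 6.459, 6.621 and 6.785 in Mkx-CreER/flox 1, 4 and 5, against 6.726 to 7.328 in the controls.

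The 479 risen genes outside the muscle list rose by 1.28 on average (SE 0.198). The slope on the muscle score predicted 0.171 (SE 0.15), and without Mkx-CreER/flox 1 the mean was 0.867 times as large (1.11, SE 0.207). These genes were chosen by their rise in the same libraries, which favours a large rise and a small slope, so neither value excludes muscle RNA or that library as a cause. With the muscle score as a covariate the median of the 485 risen genes went from 1.213 (SE 0.27) to 0.91 (SE 0.326) with 4 called, and that of the 259 fallen genes from -1.025 (SE 0.23) to -1.049 (SE 0.269) with 8 called. Since 44.9% of the variance of the muscle score lay between genotypes, a part of the rise that may come from muscle RNA was not separated from the genotype.

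Other splits of the libraries showed what chance gives. Against both controls, 1 of 100 splits (the real one) gave 744 genes, and the highest other gave 49. Against Mkx-flox/+, 1 of 35 splits (the real one) gave 1165 genes, and the highest other gave 231. Counts this large were thus rare among other groupings of the libraries. The splits do not part the genotype from the muscle share or the dissection, which may differ between the same groups. Against Mkx-CreER/+, 3 of 10 splits gave at least 1 gene, the highest other gave 8, and 10 splits are too few for a share under 0.05. Between the controls the real count was 0 genes in edgeR (798 at an unadjusted p under 0.05, 34 in DESeq2, 0 in limma voom), so all 35 splits gave as many by construction, the highest other gave 1, and the splits say nothing about chance there.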

How the results depend on the processing

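The muscle covariate with Mkx-CreER/flox 1 left out and the Schwann covariate were chosen only after the data were seen. Results are given for Mkx-CreER/flox against both controls, Mkx-CreER/+ and Mkx-flox/+, then for the controls, then for genes called against each control. DESeq2 called 1447, 123, 1830, 34 and 118 genes. limma voom called 2991, 715 and 2853, and 644 against each control. With no filter on low counts 9 were called against Mkx-CreER/+ and 9 against each control. With only the groups compared in the fit both counts were 0 in edgeR. The stricter filter ended the osteoclast list call against both controls (camera adjusted p = 0.0509) and Mkx-CreER/+ (0.0687). RLE scaling ended the erythroid list call between the controls (0.0516). The muscle covariate left 12 against both controls and 41 against Mkx-flox/+, and with Mkx-CreER/flox 1 also out the counts were 87, 8, 204, 3 and 8. With the Schwann covariate the counts were 1566, 2 and 1939, and 2 against each control. By construction the muscle covariate turned the skeletal muscle list mean to -0.129, -0.059, -0.2 and -0.141, and without Mkx-CreER/flox 1 to -0.139, -0.048, -0.23 and -0.182. With both changes oxidative phosphorylation was -0.043 against Mkx-CreER/+ and 0.099 against both controls, where its call ended (adjusted p = 0.329). The inflammatory call against both controls (0.0568) and the endothelial call between the controls (0.0652) ended there too. The Schwann covariate turned its own list to -0.153, -0.106 and -0.2. The muscle covariate also ended the osteoclast (0.115), senescence (0.0974) and adipocyte (0.0834) calls against both controls, the oxidative phosphorylation (0.0932), endothelial (0.14) and osteoclast (0.0846) calls against Mkx-CreER/+, and the cartilage (0.188), inflammatory (0.0598) and erythroid (0.357) calls between the controls. The Schwann covariate ended the mural call in the 3 comparisons of Mkx-CreER/flox (means 0.362, 0.324 and 0.4, adjusted p = 0.129, 0.104 and 0.166). It also ended the endothelial call against both controls (0.129) and Mkx-CreER/+ (0.527), the matrix-degrading call against both controls (0.0623) and Mkx-flox/+ (0.0523), the senescence (0.0996) and adipocyte (0.0526) calls against both controls, and the inflammatory call between the controls (0.0652). camera with an estimated correlation called 0, 0, 0 and 0 lists, and fry 5, 1 and 0 against both controls, Mkx-CreER/+ and between the controls. Leaving out 1 library gave 64 to 1114, 0 to 117, 455 to 1585 and 0 to 0 genes, and 0 to 108 against each control. Called lists then numbered 11 to 20, 13 to 20, 12 to 16 and 10 to 20. Skeletal muscle between the controls ranged from -0.003 (without Mkx-CreER/+ 2) to 1.025, and oxidative phosphorylation against Mkx-CreER/+ from -0.001 (without Mkx-CreER/flox 1) to 0.722. Mkx against both controls ranged from -1.973 to -2.105 and stayed called, and against Mkx-CreER/+ it was not called without Mkx-CreER/flox 4 (-1.72, adjusted p = 0.0549) or with only those groups (-1.66, 0.0575). Other than for covariates built from a list, the cause was not tested. Over all settings 124 counts stayed within 1.5 times and 53 did not. List results kept direction and call in 866 cases, lost the call in 182 and reversed in 14. Named genes kept both in 1694 cases, gained the call in 54, lost it in 489 and reversed in 0. Depth sets a floor of 0.132 to 0.346 CPM for 3 counts. No paired analysis was possible because the column numbers of Mkx-CreER/+ and Mkx-CreER/flox do not match the replicate numbers of the labels and no litter or batch is given. A replicate block was thus not run, nor was a sex covariate, all libraries being male by their Y-linked transcripts.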

Other observations

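The tests in this part were written before their results were seen. Mkx measured 92.9 CPM in Mkx-CreER/+ and 159.7 in Mkx-flox/+. The difference did not pass in edgeR over all genes (adjusted p = 0.489, unadjusted p = 0.000499). A hypothesis was that the CreER allele itself lowers Mkx function, so that Mkx-CreER/+ lies between the other genotypes. Genes were chosen with some of the Mkx-flox/+ libraries and measured with the rest, so that noise of shared Mkx-flox/+ libraries could not place it there. The same Mkx-CreER/flox libraries both chose the genes and gave the full change. Over 6 such splits Mkx-CreER/+ lay at a mean share of 0.373 of the way from Mkx-flox/+ to Mkx-CreER/flox (0.314 to 0.449, 13 to 368 genes, with 199 genes chosen by smallest p in 2 of the splits). The splits reuse the same mice, so their range holds no error between mice. The share argues against noise shared through the Mkx-flox/+ libraries as the whole cause. Chance differences of the Mkx-CreER/+ mice were not tested. A milder effect of the CreER allele may be a reason, though the muscle share was also intermediate.

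Another hypothesis was that variants flanking the targeted allele change genes near Mkx. Within 10 Mb of Mkx on chromosome 18, 4 of 60 genes (6.67%) were called against Mkx-flox/+, namely Cul2, Svil, Mir133a-1hg and Cables1, and 1160 of 15956 (7.27%) elsewhere. The odds ratio was 0.911 (95% interval 0.239 to 2.47, Fisher exact p = 1), so no excess of calls near Mkx was seen, though the interval leaves room for one. With 60 genes tested there, such variants could not give many of the calls in any case. Mkx-flox/+ carries the floxed allele too, so variants flanking that allele may not show in this comparison.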
